A study of Mus musculus with 20 samples.

How the data were processed

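RNA from the extensor digitorum longus (EDL, a fast hindlimb muscle) of male C57Bl6 mice was measured on 20 one-colour mouse expression arrays. Per the labels, a recombinant adeno-associated virus of serotype 6 was injected into the muscle of animals 8 weeks old, in 30 µL per leg. The left leg received an empty vector. The right leg of the same animal received 2 vectors, for HDAC4 and HDAC5 (class IIa histone deacetylases) with a point mutation that makes each act as a dominant negative, at 2.5e+10 vector genomes each. After 4 weeks the animals were injected with Scriptaid, a hydroxamate histone deacetylase inhibitor, or with vehicle. The dose of Scriptaid and the time between injection and collection of the tissue are not stated in the labels. The 4 groups of 5 arrays are abbreviated EV (empty vector, vehicle), HV (dnHDAC4/5, vehicle), ES (empty vector, Scriptaid) and HS (dnHDAC4/5, Scriptaid), and HS 2 stands for replicate 2 of the HS group. The sample titles of the ES group say vehicle, while its treatment entry, description and animal identifiers say Scriptaid. The latter were followed, because the identifiers pair these legs with the right legs of the Scriptaid animals.

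Per the labels' protocols, 100 ng of input RNA was labelled with Cy3 for each array. Per the file headers, arrays of the design Agilent-014868 were scanned, and Feature Extraction 9.5.1.1 with the protocol GE1-v5_95_Feb07 subtracted the background, removed a spatial trend and wrote the processed intensity per spot. These intensity values were deposited for every array. The series matrix holds a ratio, which the files show to be the processed intensity divided by one constant per array, for 23678 probes that the authors kept. The scanner files' intensity was used, since the matrix lacks dim probes. Each array has 45018 spots, of which 43379 are not controls, with 41174 probe names and 27376 gene names.

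Each processed intensity was put on the log2 scale, and the array's 75th percentile of non-control spots was subtracted. Spots that the scanner software marked as non-uniform or as population outliers were left out (12539 over all arrays). Spots of the same probe were averaged. A probe was kept when it was well above background, by the scanner software's own test, on at least 5 arrays and had at least 3 arrays left in each group, which left 23596 probes. The probe of highest mean stood for its gene, which gave 15720 genes. Gene names are those in the files. A gene reference of assembly GRCm38.p6 was used only for current names. Of 32724 accessions, 19472 matched, and 2604 probes had a different current symbol. The files do not state the build behind the probe positions, so no coordinate is given. Probes cannot tell near-identical genes apart, such as Hspa1a and Hspa1b or the Ces2 family, so their values are uncertain as to the member. Some genes that the naming rule picked are not reported here, and all counts, lists and tests include them.

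A model of the 4 group means was fitted to every gene with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), with moderated variances, two-sided tests and Benjamini-Hochberg adjustment over all genes, and a gene was called at an adjusted p under 0.05. A group has 5 arrays for each gene, less those whose spot was left out. Every adjusted p of a gene is from limma. The comparisons were the vector in vehicle animals (HV against EV), the vector in Scriptaid animals (HS against ES), Scriptaid in empty-vector legs (ES against EV), Scriptaid in dnHDAC4/5 legs (HS against HV), both treatments against neither (HS against EV), the vector averaged over both injections, and the interaction. These comparisons, the filter, the rule for naming genes, 34 gene lists and the alternatives named as planned were fixed before the data were examined. The lists were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists of one comparison, and again with an estimated correlation and with fry, which asks whether a list's genes move one way and does not compare them with other genes. Of these lists, 10 share a measured gene with another list, and each marker list of a cell type holds only genes that muscle tissue as a whole expressed above background. The rule named, per single comparison, the 10 largest rises and falls among called genes that moved the same way in all 5 animals or did not overlap between groups, or the 5 of smallest p where fewer than 5 qualified, leaders of each called list, called members of other lists, and Hdac4 and Hdac5. For the other comparisons it named the 5 genes of smallest p in each direction. Clone and locus names were passed over: 7 rises and 19 falls for the vector in Scriptaid animals, 6 and 17 for Scriptaid in dnHDAC4/5 legs.

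Each of the 5 slides held 4 arrays, 1 of every group, and the replicate number is the slide. The place on the slide was the same for a group on every slide, so place and group cannot be told apart. The animal identifiers show that EV and HV arrays of one number, and ES and HS arrays of one number, come from the same animal. For deviations from the group mean, the median correlation across genes was 0.28 (0.03 to 0.41) for the 10 pairs of one animal. It was 0.17 (-0.15 to 0.38) for the 20 pairs of other animals on one slide, and -0.08 (-0.35 to 0.44) for the 120 remaining pairs. The ranges overlap and pairs of one animal also share a slide, so the pairing rests on the identifiers. Fits with the animal as a block, here called the replicate block, and with the slide as a block, called the slide block, were therefore also planned. With the replicate block the vector averaged over both injections gave 267 called genes. The vector is confounded with the side of the body, because the dnHDAC4/5 vectors always went into the right leg. The control leg received an empty vector, so an action of the mutant proteins cannot be told apart from that of any expressed protein.

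After the data were examined, spots near the edge of the array proved to read low on the HS arrays. A fit without the last 8 of 85 columns and the first and last 10 of 532 rows (5197 non-control spots), which tested 14653 genes, was added, and its results are given beside those of all spots. That fit was also run with each array's smooth column and row trend removed (lowess, window 0.2), with the replicate block, with the slide block and leaving out each array. Other alternatives, all planned, were quantile normalization, normexp background correction (offset 50), the series-matrix values, no filter on dim probes, a filter on all 20 arrays, the mean of all probes of a gene, every probe on its own, only the groups compared, a variance trend with robust moderation, array weights, and leaving out each array.

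The steps were tested on simulated data with 200 changed genes among 15720 genes, in 10 draws. For the vector in vehicle animals, 58.7% of genes changed by log2 1 and 88% of those changed by log2 2 were recovered. For the averaged vector effect the shares were 76.8% and 94.8%. The simulated noise was independent between arrays, without the likeness of arrays of one slide or animal and without low edge spots. The shares may therefore differ in the real data, and a gene that was not called is not shown to be unchanged. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.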

Results

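Messenger RNA was measured in the EDL muscle of 10 male mice, 5 injected with Scriptaid and 5 with vehicle, with an empty vector in the left leg and dnHDAC4/5 vectors in the right leg of each. The 20 arrays fell into 4 groups of 5. The 75th percentile of the processed intensity lay between 248.4 and 608.1, and between 51.7% and 61.3% of spots were well above background. Class IIa histone deacetylases hold muscle genes down through MEF2 and are expelled from the nucleus by exercise. The design asks which transcripts a block of HDAC4 and HDAC5 changes, which a drug against histone deacetylases changes, and whether the effects resemble or modify each other.

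The native Hdac4 and Hdac5 transcripts gave no check of the vectors, since the vector sequences are not given and the probes may miss them. Over the arrays whose spot was not left out, the log2 value of Hdac4 (probe A_51_P417839) lay between 0.40 and 1.94 and that of Hdac5 (probe A_51_P278893) between 2.67 and 3.70. Hdac4 differed between legs by 0.28 ± 0.24 (SE; 5 EV and 4 HV arrays) in vehicle animals and 0.30 ± 0.23 (5 arrays of each group) in Scriptaid animals. Hdac5 differed by -0.01 ± 0.15 (4 EV and 5 HV arrays) and -0.01 ± 0.17 (5 ES and 3 HS arrays). None of these passed limma's test.

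The HS arrays read low near the edge of the array, which enters every comparison with them. On each of the 5, between 4.58% and 6.87% of spots in the edge zone read more than log2 3 below the median of the other arrays, against 0% to 0.821% on the other 15. The HS arrays also had more spots left out as non-uniform or outlying (657 to 1342, against 375 to 685) and somewhat more low spots inside the array (0.092% to 0.451%, against 0.0175% to 0.11%, and 1.53% on EV 5). The fit without edge spots is therefore not sure to be free of low spots. Of the 15720 genes tested, 1547 (9.84%) were represented by an edge probe. Called rises also fell in the zone more often than that share, which low spots alone do not explain, and the cause was not tested. Counts with HS arrays are therefore given with and without edge spots, and the adjusted p without them follows the first where it matters. The change of a gene with no spot in the zone is the same in both fits. The adjustment runs over all genes, so edge genes of small p ease the threshold for the others. Outside the zone 42 genes were called for the vector in Scriptaid animals with all spots, and 3 without edge spots. For Scriptaid in dnHDAC4/5 legs these counts were 37 and 1. Calls made only with all spots thus rest in part on edge genes.

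**Figure D1:**
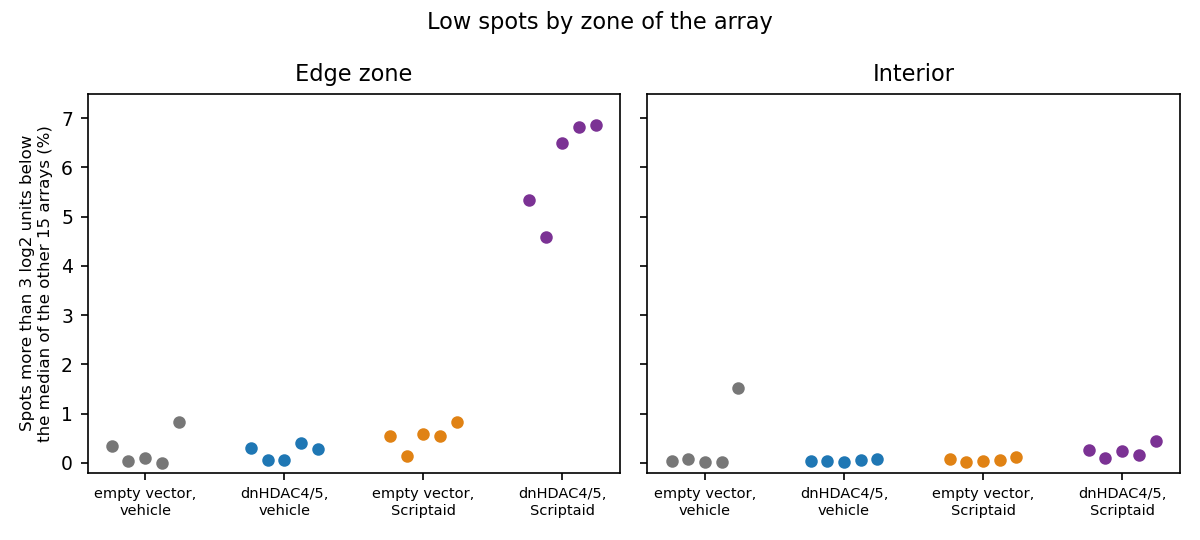
Share of spots (percent, y) more than log2 3 below the median of the other arrays, by group (x), in the edge zone and in the interior; points are arrays. In the edge zone the HS arrays lie between 4.58% and 6.87% and the 15 others at or under 0.821%.

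The vector in vehicle animals asks what the dnHDAC4/5 vectors changed against an empty vector, without the drug. limma called 0 genes (smallest adjusted p = 0.191), with 729 of 15720 at an unadjusted p under 0.05. Without edge spots it called 0, with 710 of 14653. Chance alone would put about 5% of the genes tested under that p, and neither count exceeds that share. Among the rises, the genes of smallest p, which did not pass, were Chrna9, the α9 subunit of a nicotinic acetylcholine receptor best known from the inner ear, and Igfn1, an immunoglobulin-like protein of the Z-disc. Chrna9 was higher by log2 5.12 ± 0.95 and Igfn1 by 2.90 ± 0.54 in right legs, in 5 of 5 animals (adjusted p = 0.191 each). Chrna9 was not above background in EV legs, so its fold is a bound, at least 11.6-fold. It was not above background on every HV array either, so the rise in 5 of 5 animals includes values under background. Tlr5, the receptor for flagellin, differed by 1.07 ± 0.24, Stbd1, which tethers glycogen to membranes, by 1.23 ± 0.27, and Gsdma, a pore-forming gasdermin, by 2.50 ± 0.56 in 4 of 5 animals. Lower values came from the embryonic myosin Myh3 (-1.41 ± 0.26), the coiled-coil protein Ccdc146 (-1.39 ± 0.30), the ubiquitin ligase Trim35 (-0.83 ± 0.19), Hhatl, an acyltransferase-like protein of the sarcoplasmic reticulum (-0.85 ± 0.21), and the myosin light chain Myl10 (-1.66 ± 0.41). Without HV 5 limma called 3 genes: Chrna9 (adjusted p = 0.000106), Igfn1 (0.0205) and Gsdma (0.042).

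Of the 34 lists, 6 stood out from the other genes in this comparison at the preset correlation, and none did with an estimated one. Schwann-cell markers, which include the myelin genes Mbp (-1.24, on 2 of its 3 probes) and Cnp (-0.54), had a median of -0.65, with 9 of 10 members lower (adjusted p = 3.85e-06, and 0.234 with an estimated correlation). Slide medians ran from -1.9 to 0.01, with 4 of 5 slides lower. Atrophy and autophagy genes had a median of 0.19 with 13 of 14 higher (adjusted p = 0.000196, and 0.228 with an estimated correlation). The translation repressor Eif4ebp1 (0.67, with 0.52 and 0.67 on its 2 probes), the autophagosome protein Map1lc3a (0.58) and the ubiquitin ligase Fbxo32 (0.47) led. With the mean of all probes Eif4ebp1 was -0.05 ± 0.72. On arrays where the spot of 1 probe was left out, that mean takes the level of the other alone. The value is therefore no disagreement of the probes. The median of the atrophy list was 0.11 without EV 1 and 0.08 without HV 4, and the call was kept. Heat shock proteins had a median of 0.37 with 11 of 12 higher (adjusted p = 0.000813, estimated 0.228), led by the small chaperone Hspb8 (0.47), its partner Bag3 (0.32) and Hspa1a (1.55). Slide medians of the heat shock list ran from 0.02 to 0.54, and the median was 0.23 without EV 1. Denervation and neuromuscular junction genes had a median of 0.37 with 12 of 16 higher (adjusted p = 0.015, estimated 0.228), led by Gadd45a (1.11), the receptor anchor Rapsn (0.35) and the receptor subunits Chrna1 (0.69) and Chrng (0.71, on 1 of its 2 probes only). That call was lost without EV 4 or HV 2 (adjusted p up to 0.0564). Slow-fibre genes, such as the troponin Tnnc1 (-1.72, an edge probe) and the light chain Myl2 (-1.86), had a median of -0.51 with 9 of 12 lower (adjusted p = 0.0282, estimated 0.677, 0.0843 with the replicate block, 0.0679 with the slide block, 0.205 without edge spots). Red blood cell markers had a median of -0.72 with 6 of 6 lower (adjusted p = 0.0473, estimated 0.852, 0.0851 with the replicate block, 0.0559 with the slide block, 0.0558 without edge spots). The slow-fibre call was lost without EV 1, EV 2, EV 3, HV 4 or HV 5 (up to 0.217) and the red blood cell call without EV 1, EV 3, HV 1, HV 4 or HV 5 (up to 0.743). Over all genes 0 members of these lists passed; adjusted over the list alone, 2 Schwann-cell and 2 atrophy genes did.

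The vector in Scriptaid animals repeats the question under the drug. limma called 195 genes, 84 higher and 111 lower in right legs, of which 153 were edge-zone genes, 55 higher and 98 lower; without edge spots it called 3, all higher, and 1307 at an unadjusted p under 0.05. Those 3 were Chrna9, the secreted phospholipase Pla2g5 and the carboxylesterase Ces2c. Chrna9 rose by log2 6.07 ± 0.95 (adjusted p = 0.00197, at least 25.7-fold, since ES legs were not above background), and Pla2g5 by 4.17 ± 0.69 (0.00318). Ces2c rose by 3.08 ± 0.50 (0.0028). Each rose in 5 of 5 animals, and the adjusted p without edge spots was 0.0461 for all of them. In that fit 1 gene was called with the replicate block and 2 with the slide block, so neither block kept all 3. Within slides Chrna9 ran from 5.26 to 7.38, Pla2g5 from 3.55 to 5.28 and Ces2c from 1.92 to 4.31. Igfn1 rose by 2.98 ± 0.54 (adjusted p = 0.00665, 0.0807 without edge spots) and a further carboxylesterase, Ces2b, by 2.55 ± 0.54 (0.023, 0.132). The tendon transcription factor Scx rose by 1.57 ± 0.35 (0.0315, 0.166) and Tlr5 by 1.16 ± 0.24 (0.0168, 0.111), again in 5 of 5 animals. Leaving out 1 array with edge spots excluded kept a call only without HS 2 (Chrna9, Ces2c) or HS 3 (Pla2g5, Ces2c), and adjusted p reached 0.164. With all spots Tlr5 was lost without HS 5 (0.0543), Ces2b without ES 1, ES 2, HS 1, HS 4 or HS 5 (up to 0.0758) and Scx without ES 1, ES 2, ES 3, ES 5, HS 4 or HS 5 (up to 0.0923). The count ranged from 112 (without ES 1) to 380 (without HS 2). It was 116 without ES 2, 117 without ES 4 and 127 without HS 5, and without edge spots it was 5 without HS 2, 2 without HS 3 and 0 without each of the others.

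The leading falls in this comparison were all of edge probes, on the arrays with low edge spots. They included Cdkn2d (-4.73 ± 0.58), P2ry6 (-4.47 ± 0.41), Mrpl1 (-4.44 ± 0.43), Mpp3 (-4.21 ± 0.44), Pogz (-4.08 ± 0.41), Ccdc41 (-4.07 ± 0.19), Stx2 (-4.06 ± 0.60) and the endothelial cadherin Cdh5 (-3.97 ± 0.24). The HS arrays were all under background for P2ry6, Pogz and Cdh5, so those sizes are not precise. Where another probe lay inside the array, the brightest such probe gave 0.12 for Mrpl1, 0.18 for Ccdc41 and 0.16 for Stx2. Ccdc41 has 2 probes inside the array, with a median of -0.05. The calcium-binding protein Casq1 of fast fibres, a called list member, had a change of -10.03 (adjusted p = 1.02e-06, 3 of 5 animals measured) on an edge probe alone, and so did Sox10 (-1.52), Bhlhe40 (-2.95) and Oas1a (-1.94). Rises on edge probes were those of Blnk (1.32), Dedd2 (1.17), Fam164c (1.1) and Ankrd11 (1.11). Without ES 2 the adjusted p of Blnk was 0.0676, without HS 5 that of Ankrd11 was 0.0714, and without HS 1 or HS 4 that of Dedd2 was up to 0.0701. No statement about these transcripts is drawn from edge probes.

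Heat shock proteins were again higher in right legs of Scriptaid animals, with a median of 0.40 and 12 of 12 higher (adjusted p = 0.0005, 0.423 with an estimated correlation), and slide medians from 0.27 to 0.71. The co-chaperone Dnajb1 passed (0.81 ± 0.19, adjusted p = 0.0453, and 0.19 without edge spots; lost without any 1 of the 5 ES arrays, HS 1, HS 4 or HS 5, up to 0.125). With the slide block it did not pass (0.0564). Hspa1a (2.97, adjusted p = 0.117, 0.0372 with the replicate block) and Hspa1b (3.01) did not pass, and 3 members did adjusted over the list alone. Atrophy and autophagy genes had a median of 0.26 with 13 of 14 higher (adjusted p = 0.0279, estimated 0.843), lost without ES 1 or HS 4 (up to 0.0661). The p53 targets, including the death genes Bbc3 (0.49) and Bax (0.37) and the arrest gene Cdkn1a (0.67), had a median of 0.25 with 13 of 15 higher (adjusted p = 0.0377, estimated 0.843). The call was lost without ES 1, ES 3, ES 5, HS 2 or HS 4 (up to 0.177). Adjusted over the list alone 3 p53 targets passed, and over all genes 0 did, but Bbc3 passed with the replicate block (0.037) and the slide block (0.0433). Immediate early genes, led by the growth regulator Myc (0.93; called without HS 3, adjusted p = 0.0418, and with the replicate block, 0.0277, or the slide block, 0.0192), had a median of 0.38 with 14 of 16 higher (adjusted p = 0.0485, estimated 0.843, 0.0563 with the slide block). The call was lost without any 1 array but ES 3 or HS 1 (up to 0.21). Adipocyte markers such as Cidec (2.19) and Cfd (2.13) had a median of 1.55 with 10 of 11 higher (adjusted p = 0.0377, estimated 0.843, 0.0736 with the replicate block). They lost the call without ES 1, ES 3, ES 5, HS 2, HS 3 or HS 5 (up to 0.216). Endothelial markers had a median of -0.14 and a mean of -0.51 that rests on edge probes such as that of Cdh5 (adjusted p = 0.0279, estimated 0.843, 0.15 without edge spots, and up to 0.216 without ES 3 or HS 2).

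The vector averaged over both injections uses all 10 animals. limma called 172 genes, 82 higher and 90 lower, and 34 without edge spots (20 higher, 14 lower; 1559 at an unadjusted p under 0.05). With all spots 73 of the called genes were edge genes. Chrna9 rose by 5.60 ± 0.67 (adjusted p = 0.000248, 0.0015 without edge spots) and Igfn1 by 2.94 ± 0.38 (0.000571, 0.00224). Pla2g5 rose by 3.36 ± 0.49 (0.00222, 0.00711) and Tlr5 by 1.12 ± 0.17 (0.00238, 0.00711), all 4 in 10 of 10 animals, and Ces2c by 2.38 ± 0.36 in 9 of 10 (0.00238, 0.00711). Chrna9 was above background on 9 arrays, 4 of HV and 5 of HS, so its size is uncertain. Without edge spots the falls of smallest p were those of Ccdc146 (-1.33 ± 0.21, adjusted p = 0.00949), Hhatl (-0.87 ± 0.15, 0.0155) and Mmd, a membrane protein of the adiponectin-receptor family (-0.68 ± 0.12, 0.0248). They were followed by Cdyl, a chromodomain corepressor (-0.69 ± 0.13, 0.0248, on 1 of its 2 probes) and Ppapdc3, a nuclear-envelope phosphatase-like protein (-0.84 ± 0.15, 0.0248, in 9 of 10 animals).

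Of these 34 genes, 11 were called whichever of the 20 arrays was left out, among them Chrna9, Igfn1, Pla2g5, Ces2c, Tlr5, Ccdc146 and Hhatl; the glycogen tether Stbd1, Gsdma and the γ-glutamyltransferase Ggt6 were chosen for mention after their values were seen. The other named falls were lost in part, Mmd up to 0.0676, Cdyl up to 0.0689 and Ppapdc3 up to 0.0702, the highest values being those without HV 1. Mmd was lost without HV 1, HV 2, ES 1, ES 2, ES 5 or HS 4. Cdyl was lost without EV 2, EV 4, HV 1, HV 2, HV 4, ES 1, ES 2, ES 5 or HS 5. Ppapdc3 was lost without 12 of the 20 (EV 2, EV 3, EV 4, HV 1, HV 2, HV 4, ES 1, ES 2, ES 4, ES 5, HS 4 and HS 5). The count without edge spots ranged from 11 (without HV 1 or HV 2) to 215 (without HV 5), and was 98 without HS 3, 79 without HV 3, 73 without HS 2, 45 without ES 3 and 12 to 29 without each of the others. With all spots it ran from 78 (without HV 1) to 330 (without HV 5), with 90 without EV 2, 102 without EV 4 and 88 without HV 2. It was 89 without HV 4, 97 without ES 1, 80 without ES 2, 96 without ES 4, 94 without HS 5 and 291 without HS 2. The 5 falls of smallest p with all spots, of Ccdc41 (-1.92), Cdh5 (-1.97), Casq1 (-5.10), Chsy1 (-2.02) and Chd1 (-1.88), were those of edge probes. The brightest interior probe gave -0.01 for Ccdc41 and 0 for Chd1.

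**Figure D2:**
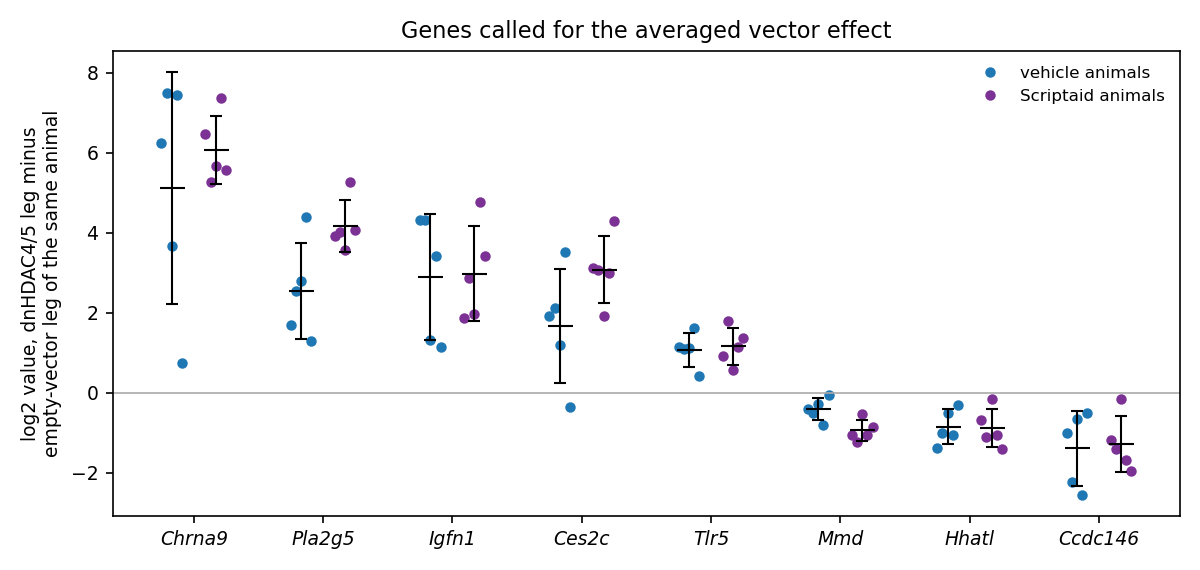
Right leg (dnHDAC4/5) minus left leg (empty vector) of each animal in log2 (y) for 8 genes called for the averaged vector effect (x); points are animals by injection and bars the mean ± SD. Chrna9, Igfn1, Pla2g5 and Tlr5 lie above 0 in 10 of 10 animals, and Ccdc146, Hhatl and Mmd below 0 in 10 of 10.

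Averaged over both injections, heat shock proteins had a median of 0.38 with 11 of 12 higher (adjusted p = 2.01e-05, 0.172 with an estimated correlation). Atrophy and autophagy genes had a median of 0.25 with 13 of 14 higher (0.000351, estimated 0.328), and no single array decided either call, though the atrophy median was 0.16 without HV 4. Over all genes 0 heat shock genes and 1 atrophy gene, Eif4ebp1, passed (adjusted p = 0.0463, 0.0706 without edge spots), and 4 of each did adjusted over the list alone. Schwann-cell markers had a median of -0.32 with 8 of 10 lower (adjusted p = 0.00436, estimated 0.736; -0.17 without EV 1), and their 1 member past the threshold, Sox10 (-1.14), rests on an edge probe. In Scriptaid animals alone the median was -0.01 (adjusted p = 0.459). Macrophage markers had a median of 0.34 with 16 of 18 higher (0.0332, estimated 0.736). Immediate early genes had a median of 0.25 with 13 of 16 higher (0.0332, estimated 0.736, 0.054 with the slide block), of which Myc passed (0.81, adjusted p = 0.0267, 0.0502 without edge spots) and 2 did adjusted over the list alone. The macrophage call was lost without EV 4, EV 5, HV 2, HV 3, ES 2, ES 4, HS 2, HS 3 or HS 5 (up to 0.216). The immediate early call was lost without EV 4, EV 5, HV 2, ES 1, ES 5, HS 2 or HS 3 (up to 0.19).

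Scriptaid in empty-vector legs asks what the inhibitor did in muscle that had received only the empty vector. limma called 0 genes, against 603 at an unadjusted p under 0.05 (smallest adjusted p = 0.264). Among the rises, the genes of smallest p, which did not pass, were Fam107a, an actin-binding stress protein (1.76 ± 0.31), and Fkbp5, a co-chaperone that restrains the glucocorticoid receptor (1.04 ± 0.20). The arrestin-like Arrdc2 (1.11 ± 0.22) and the lipid-droplet protein Plin4 (0.68 ± 0.13) followed, and the adjusted p was 0.264 for each of the 4. Next came the mitochondrial carrier Slc25a25 (1.12 ± 0.23, 0.384). The groups did not overlap for Fkbp5, Arrdc2 and Plin4. Fam107a was called without EV 1 (adjusted p = 0.0134) and Slc25a25 without EV 3 (0.00718). Lower values came from Il17re, a subunit of an interleukin-17 receptor (-1.30 ± 0.30, adjusted p = 0.51), and the centriole protein Cep164 (-0.72 ± 0.18, 0.731, on 1 of its 2 probes). The cyclin Ccnd1 (-0.57 ± 0.16), the steroid reductase Srd5a1 (-0.73 ± 0.20) and the desmosome protein Kazn (-0.66 ± 0.19) were also lower.

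The list of genes that respond to glucocorticoids was the clearest list result of the series. In empty-vector legs its median was 0.56 higher with Scriptaid, with 13 of 14 members higher (adjusted p = 2.87e-14). It was called with an estimated correlation (0.00192) and with fry (0.000762), without any 1 array (up to 7.48e-10), and slide medians ran from 0.54 to 0.66. Fkbp5, the kinase Map3k6 (0.74), the clock gene Per1 (0.64, an edge probe) and the metallothionein Mt1 (1.09) led; adjusted over the list alone 7 members passed, and over all genes 0. In dnHDAC4/5 legs the median was 0.61 with 14 of 14 higher (adjusted p = 1.11e-08, estimated 0.0215, fry 0.000167, up to 2.39e-06 without 1 array), and slide medians ran from 0.13 to 1.17. There 4 members passed over all genes with all spots, Per1 on an edge probe, and none without edge spots; 7 passed adjusted over the list alone. The left and right legs come from the same animals, so the result in dnHDAC4/5 legs is no independent repeat of that in empty-vector legs. Of the 14 members, 4 also stand in another list (Klf15, Mt1, Mt2 and Per1).

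**Figure D3:**
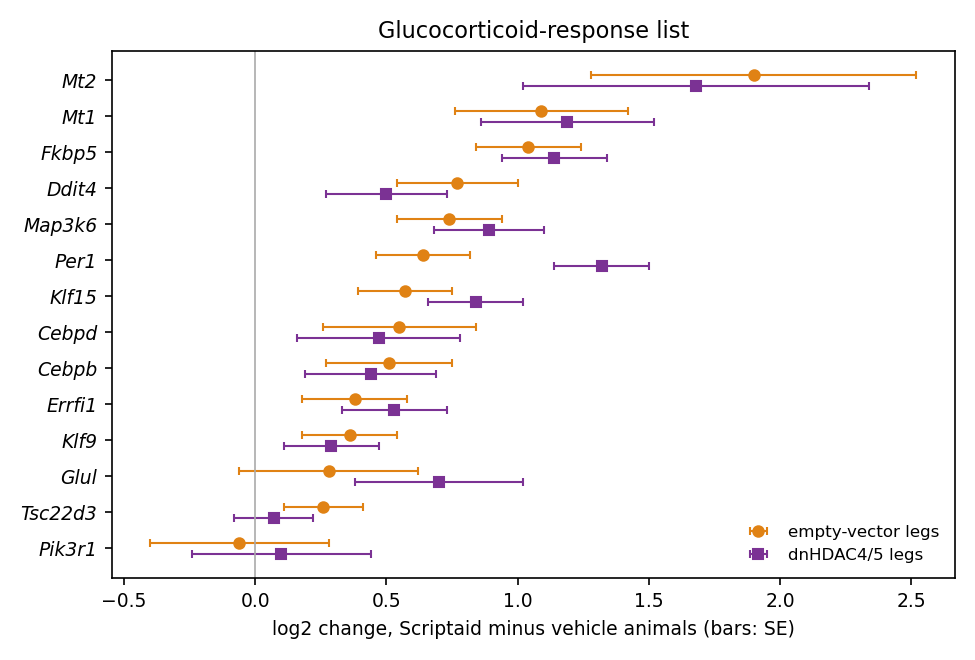
Log2 change with Scriptaid (x, ± SE) of the 14 measured genes of the glucocorticoid list (y), in empty-vector legs (circles) and dnHDAC4/5 legs (squares). Members lie above 0 in 13 of 14 cases in empty-vector legs and 14 of 14 in dnHDAC4/5 legs, and Per1 rests on an edge probe.

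Scriptaid also went with higher exercise-responsive regulators in empty-vector legs, a median of 0.26 with 17 of 18 higher (adjusted p = 0.000161, 0.0831 with an estimated correlation). Klf15, a regulator of amino acid breakdown (0.57), the fatty acid receptor Ppara (0.71) and the mitochondrial coactivator Ppargc1a (0.35) led. Genes of branched-chain amino acid breakdown, led by Mccc2 (1.34, 0.68 without EV 5) and Acadsb (1.5, 0.14 without EV 5), had a median of 0.17 with 14 of 15 higher (0.00203, estimated 0.392). It was 0.11 without EV 1 and 0.1 without ES 5, and the call was kept. Genes of fatty acid uptake and oxidation had a median of 0.18 with 17 of 20 higher (0.00586, estimated 0.689), lost without EV 2 or EV 4 (up to 0.092). Atrophy and autophagy genes, led by the transcription factor Foxo1 (0.60) and Fbxo32 (0.52), had a median of 0.12 with 10 of 14 higher (0.0339, estimated 0.556, 0.068 with the slide block). That call was lost without EV 1, EV 3, EV 5, ES 2 or ES 3 (up to 0.105). Immediate early genes had a median of 0.32 (0.0339, estimated 0.689), lost without EV 3, EV 4, EV 5 or ES 3 (up to 0.554). Adjusted over the list alone 1 atrophy gene passed, and over all genes no member of these lists did.

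Lower lists in the same comparison leaned on the array EV 1. Extracellular matrix genes, led by Thbs4 (-0.68) and Col12a1 (-1.14), had a median of -0.35 with 21 of 24 lower (adjusted p = 0.000642, estimated 0.689, 0.0976 without EV 1). With an array left out that median ran from -0.49 to -0.11, and it was -0.21 without ES 2. Cell cycle genes had a median of -0.56 with 14 of 17 lower (0.00152, estimated 0.619, 0.3 without EV 1), and adjusted over the list alone 1 member, Ccnd1, passed. The cell cycle median ran from -0.65 to -0.16 with an array left out. Tendon and fibroblast markers such as Tnmd (-1.11) had a median of -0.38 with 12 of 13 lower (0.00225, estimated 0.543, up to 0.092 without EV 1 or EV 2), and the median was lower on 2 of the 5 slides. Slow-fibre genes had a median of -0.66 with 10 of 12 lower (0.00288, estimated 0.451, 0.0661 without EV 1; median -0.36 without EV 2).

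Scriptaid in dnHDAC4/5 legs asks for the drug's effect in the legs that received the vectors. limma called 202 genes, 100 higher and 102 lower, of which 165 were edge genes (71 higher, 94 lower), and 1 without edge spots (1125 at an unadjusted p under 0.05). That gene was Slc16a12, a creatine transporter of the monocarboxylate carrier family, which fell by 0.84 ± 0.13 (adjusted p = 0.0416 without edge spots; kept without HV 4 or HS 2 only, and up to 0.125 without another array). This call was not kept with the replicate block. With all spots Arrdc2 rose by 1.20 ± 0.22 (adjusted p = 0.00546, 0.0628 without edge spots) and Fkbp5 by 1.14 ± 0.20 (0.00434, 0.0628). Fam150b, a ligand of the kinase Alk, rose by 2.02 ± 0.33 (0.00247, 0.0535; at least 1.34-fold, since HV legs were not above background). The groups did not overlap for these 3 genes. Klf15 (0.84 ± 0.18, 0.0199, 0.169 without edge spots), Map3k6 (0.89 ± 0.21, 0.0441, 0.212), the transcription factor Klf4 (0.78 ± 0.18, 0.0348, 0.195) and Plin4 (0.66 ± 0.13, 0.0171, 0.164) also passed with all spots. Klf15 was lost without HV 3, HS 1 or HS 5 (up to 0.0603), and Plin4 without HV 1, HS 1 or HS 3 (up to 0.0644). Klf4 was lost without HV 1, HV 4, HV 5, HS 1, HS 3 or HS 4 (up to 0.106) and Map3k6 without any array but HV 2, HS 2 or HS 3 (up to 0.158). Myh3 rose by 1.09 ± 0.26 (0.0441, 0.212 without edge spots, 0.0774 with the replicate block), and was lost without any array but HV 3, HS 3 or HS 4 (up to 0.127). Without edge spots the nuclear receptor Nr1i3 was lower by 1.78 ± 0.32 and missed the threshold (0.0628).

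Edge probes gave the largest changes here too: Casq1 (-9.72), Preb (-6.65, with 0 inside the array), Rnf216 (-5.59, with -0.27 inside), Rpl21 (-4.90) and Ano6 (-4.71) among the falls, and Per1 (1.32), Eln (1.07) and Thap4 (1.03) among the rises. The count ranged from 133 (without HV 2) to 476 (without HS 2), and without edge spots from 0 to 31 (without HS 2), being 2 without HV 3 and 1 without HV 4.

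Beside the glucocorticoid list, exercise-responsive regulators had a median of 0.29 with 17 of 18 higher in dnHDAC4/5 legs (adjusted p = 0.00134, estimated 0.135). Klf15 passed over all genes, and 3 members did adjusted over the list alone. Ppara (0.83, adjusted p = 0.102) and Ppargc1a (0.56, 0.0999) passed only without HS 2 (0.0329 and 0.0338) or, for Ppara, with the slide block (0.0102). Genes known to rise with histone deacetylase inhibitors in general had a median of 0.20 with 11 of 16 higher (0.0118, estimated 0.135), led by Klf4 and Mt1 (1.19, adjusted p = 0.098); 1 member passed over all genes and 2 adjusted over the list alone. In empty-vector legs that list had a median of 0.10 (adjusted p = 0.203). Extracellular matrix genes, led by Thbs4 (-0.72), the collagen Col1a2 (-0.69, called with the slide block, 0.0463) and Col12a1 (-1.93), had a median of -0.33 with 23 of 24 lower (0.000311, estimated 0.664, 0.0598 without HS 4). Tendon and fibroblast markers had a median of -0.33, a mean of -0.79 and 8 of 13 members lower (0.0118, estimated 0.664, 0.0656 without HS 4, 0.0659 without edge spots), with 3 past the threshold adjusted over the list alone. Immediate early genes, with Fos at 1.64, had a median of 0.38 with 15 of 16 higher (0.013, estimated 0.664), lost without HV 5, HS 2 or HS 3 (up to 0.105). Red blood cell markers had a median of 1.18 with 6 of 6 higher (0.013, estimated 0.664), lost without HV 4 or HS 2 (up to 0.389). Adipocyte markers had a median of 0.69 with 11 of 11 higher (0.0188, estimated 0.664), lost without HV 1, HV 5, HS 2 or HS 5 (up to 0.226). Fast-fibre genes had a median of -0.09 and a mean of -0.85 that rests on Casq1 (0.0176, estimated 0.827, 0.135 without edge spots, and up to 0.226 without HV 1, HV 5, HS 3 or HS 4).

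Both treatments against neither gives the joint effect. limma called 376 genes, 208 higher and 168 lower, of which 222 were edge genes, and 17 without edge spots (13 higher, 4 lower; 1848 at an unadjusted p under 0.05). Without edge spots Arrdc2 rose by 1.47 ± 0.22, Fam107a by 2.00 ± 0.31 and Chrna9 by 6.01 ± 0.95 (at least 21.6-fold), at an adjusted p of 0.0231 each, Fbxo32 by 1.02 ± 0.16 (0.0364) and Mt1 by 1.92 ± 0.33 (0.0377). Mmd fell by 0.92 ± 0.17 and Slc16a12 by 0.68 ± 0.13 (0.048 each), and the signalling regulator Rgs11 by 1.24 ± 0.22 (0.0377; at least 1.77-fold, HS legs being under background). Each of the 17 was lost without HS 1 or HS 4, Fam107a also without EV 2 (up to 0.0855), and Chrna9 without EV 2 or EV 5 (up to 0.0867). Beside HS 1 and HS 4, Fbxo32 was lost without EV 2, EV 3, EV 5 or HS 5 (up to 0.0867) and Mt1 without EV 2, EV 4 or EV 5 (up to 0.0898). Arrdc2 reached 0.0676. The falls were lost without 6 (Mmd, up to 0.114), 7 (Slc16a12, up to 0.114) and 8 (Rgs11, up to 0.0867) of the 10 arrays, EV 2, EV 3, EV 4 and EV 5 among them each time. The count was 0 without HS 1 or HS 4, 1 without EV 2, 2 without EV 5, 5 without EV 4, 7 without HS 5, 8 without EV 3, 37 without HS 3 and 156 without HS 2. With all spots it was 204 without EV 2, 217 without EV 4, 240 without HS 5, 243 without HS 4, 245 without HS 1, 248 without EV 1 and 776 without HS 2.

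The glucocorticoid list had a median of 0.66 in this comparison with 12 of 14 higher (adjusted p = 1.52e-07, estimated 0.039, 0.0626 when edge spots were also left out). Atrophy and autophagy genes had a median of 0.47 with 12 of 14 higher (0.00053, estimated 0.194), and immediate early genes 0.65 with 15 of 16 (0.000832, estimated 0.393). Heat shock proteins had a median of 0.31 with 11 of 12 (0.00332, estimated 0.238), and exercise-responsive regulators 0.37 with 14 of 18 (0.00426, estimated 0.194). The inhibitor-response genes had a median of 0.26 with 12 of 16 (0.0164, estimated 0.194, 0.0727 without edge spots). In that order, with the glucocorticoid list first, 5, 2, 1, 1, 1 and 3 members rose over all genes, and adjusted over the list alone 9, 6, 5, 3, 4 and 4. These counts are with all spots. Without edge spots only Fkbp5 (adjusted p = 0.0377), Mt1 (0.0377) and Fbxo32 (0.0364) among these members passed over all genes.

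The interaction asks whether Scriptaid changed the vector's effect. limma called 28 genes, 3 higher and 25 lower, all of them on edge probes, and 0 without edge spots. In the latter fit 316 of 14653 genes had an unadjusted p under 0.05, fewer than the 5% that chance alone would give. Outside the edge zone the smallest p belonged to Myh3, for which the vector's effect was 1.75 ± 0.37 higher with Scriptaid (adjusted p = 0.0813 with all spots, 1 without edge spots). Myh3 was called without HV 3, HS 3 or HS 4 (down to 0.0271). Of the lists, 5 were called, and none with an estimated correlation: red blood cell markers (1.22, adjusted p = 0.0311, estimated 0.855), adipocyte markers (1.54, 0.0464, estimated 0.855), slow-fibre genes (0.58, 0.0464, estimated 0.855), Schwann-cell markers (0.52, 0.0464, estimated 0.885) and endothelial markers (-0.15, 0.0311, estimated 0.885). With the replicate block the adjusted p was 0.0857, 0.0902, 0.0891 and 0.0891 for the first 4, with the slide block 0.0672 for the adipocyte and Schwann-cell lists and 0.0881 for the slow-fibre list, and at 0.05 for the red blood cell and endothelial lists it lay at the threshold. It was, without edge spots, 0.189 for the slow-fibre and endothelial lists. No list was left without EV 1, EV 2, HV 1, HV 5, ES 5 or HS 2. Beside these, the red blood cell and Schwann-cell calls were lost without EV 3 or HV 4 (up to 0.257 and 0.282). The Schwann-cell call was also lost without ES 3, HS 1, HS 3 or HS 4, and the endothelial call without EV 4, HV 3 or ES 3 (up to 0.222). The adipocyte call was lost without EV 3, HV 4, ES 1, ES 3, ES 4, HS 3 or HS 5, and the slow-fibre call without EV 3, HV 4, ES 1, ES 2, ES 3, HS 1 or HS 3 (up to 0.257 each). The gene count was 57 without HS 2.

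Several lists, most of them of metabolism and immunity, passed in none of the 7 comparisons. Their smallest adjusted p was 0.127 for oxidative phosphorylation (median 0.12, averaged vector effect), 0.193 for the TCA cycle (0.19, both treatments), 0.376 for lipid synthesis and storage (0.09, averaged vector effect) and 0.468 for glucose uptake, glycogen and glycolysis (0.02, empty-vector legs). For HDACs, corepressors and MEF2 it was 0.054 (0.13, vector in vehicle animals), for muscle regeneration 0.068 (-0.15, Scriptaid in empty-vector legs). For the unfolded protein response it was 0.363 (0.08, averaged vector effect), for NRF2 targets 0.297 (0.12, averaged vector effect) and for the circadian clock 0.621 (-0.02, vector in vehicle animals). For interferon-stimulated genes it was 0.312 (0.05), for antigen presentation 0.108 (0.18; 0.0369 with the replicate block) and for B and plasma cells 0.258 (-0.47), all for the vector in vehicle animals, for T and NK cells 0.476 (-0.11, vector in Scriptaid animals) and for neutrophils 0.177 (1.66, interaction). Adjusted over the list alone, the averaged vector effect reached the stress-pathway genes Xbp1 (0.47), Sdf2l1 (0.48), Manf (0.47) and Atf4 (-1.17, an edge probe) and the lipid genes Srebf1 (0.59) and Scd2 (0.52), and over all genes none of these passed. For the clock and fast-fibre lists the median, the mean and the test differed in sign in several comparisons, as for the clock in Scriptaid animals (median 0.09, mean -0.18).

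The similarity of the vector and Scriptaid effects was measured by the correlation across genes of HV against EV with ES against EV. It was 0.43, but both differences share the EV arrays, and 200 simulations without any effect gave 0.49 on average (-0.11 to 0.83). With the EV arrays split between the differences the mean of 20 splits was -0.11 (-0.20 to 0). The simulated groups were drawn with replacement from the deviations of all 20 arrays, HS arrays included, and without regard to slides. Without edge spots the correlation was 0.44, and the simulations gave 0.45 (0.02 to 0.83). The agreement of the vector effect between vehicle and Scriptaid animals, which share no array, was 0.20 across 15720 genes, with 60% of genes of the same sign; genes are not independent replicates. Swapping legs within animals gave a correlation as high in 74 of 1024 swaps (one-sided exact permutation p = 0.0723, 0.0527 without edge spots, and 0.0469 with trends also removed).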

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

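The tests of the edge zone, of the interior probes, of surface trends and of the general inhibitor response, and every value without edge spots, were chosen only after the results they bear on had been seen. Within a group, an array was picked out when its gap to the nearest other array was large against the whole range of the group. Chance alone picks out about 1 in 20 groups. Of 693 sets of values of named genes 42 (6.06%) and of 24 sets of array measures 2 (8.33%) were picked out, so the number as a whole is near what chance gives. The arrays with the most such genes were HS 2, EV 1, EV 4 and EV 5, with 5 each.

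Red blood cell transcripts set EV 1 and HS 2 apart, and slow-fibre transcripts HS 2, ES 4 and HV 4. Slc4a1, the anion exchanger of red blood cells, had a log2 value of 2.25 on EV 1 (other EV arrays -4.17 to -3.10) and 2.96 on HS 2 (other HS arrays -4.84 to -3.32). The red-cell membrane protein gene Epb4.2 stood at -2.55 on EV 1 (others -6.97 to -6.02), and the slow myosin Myh7 at 4.78 on HS 2 and 3.86 on ES 4. The cyclin Ccnb2 stood at 1.14 on HS 2. The slow light chain Myl2 stood at -2.18 on HV 4 (others 1.37 to 2.76), and Trim63, a ubiquitin ligase of atrophy, at 2.58 on HS 3.

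The array EV 5 was low for the leucine-breakdown gene Mccc2 (-4.59), the acyl-CoA dehydrogenase gene Acadsb (-2.94) and the immediate early gene Ier2 (-4.89), and high for Plin4 (5.83) and Clta (4.61). Its share of low spots inside the array was 1.53%, against 0.0219% to 0.0876% on the other EV arrays. EV 4 stood apart for Hdac5 (2.67), Ppara (1.29), Slc16a12 (-2.75), Trib2 (2.02) and Camsap2 (0.34), and EV 1 for Rgs11 (-2.95), Mcm2 (-2.36) and Heatr5a (1.59), the last of which was 1.97 on HS 2. On EV 3 Slc25a25 stood at 3.79, Ggt6 at -5.97 and Ano6 at 2.52. HV 3 had 227 saturated spots, against 156 to 172 on the other HV arrays, and Cdkn2d stood there at -1.47.

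The remaining single values were Chrna9 at -5.13 on ES 4, Prtg at -2.55 on ES 3, Bhlhe40 at 1.02 and Dedd2 at 0.65 on ES 5, Mcm2 at -5.75 on ES 5, Chsy1 at -1.58 and P2ry6 at -1.01 on ES 2, and Abcb9 at -0.36 on ES 1. On HV arrays they were Casq1 at 6.42 on HV 5, Oas1a at -3.54 on HV 4 and Rnf216 at 1.1 on HV 1. On HS arrays they were Zfhx4 at -4.77 on HS 1 and Zmpste24 at -3 on HS 5, beside Zmpste24 at 1.29 on ES 4.

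Between the sets of animals, the vector's effect differed by the test of the interaction for 8 named genes, all on edge probes: Rttn (0.99), Far1 (0.95), Clta (0.85), Ccdc41 (-4.29), Cdh5 (-4.01), Casq1 (-9.86), Rpl21 (-4.89) and Chsy1 (-3.80), as Scriptaid minus vehicle animals in log2. It also differed for the slow-fibre (median 0.58), adipocyte (1.54), endothelial (-0.15), Schwann-cell (0.52) and red blood cell (1.22) lists. No list among these passed with an estimated correlation.

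The deep falls on the HS arrays were set against a fault of the array surface and against lower transcripts. Of 156 spots in the edge zone that have a copy of the same probe inside the array, between 7.05% and 10.9% read low against that copy on each HS array, and at most 4.49% on any other (EV 5). For the 30 of 98 edge genes called lower for the vector in Scriptaid animals that have another probe inside the array, the median change of the inside probes was -0.02 (quartiles -0.14 to 0.11), against -2.96 for their edge probes. These values argue against lower transcripts as the cause for the 30 genes as a set, though not for each of them. The inside probes gave -0.94 for Sall4 (edge -2.49), -0.54 for Ano6 (-5.07) and -0.43 for E130203B14Rik (-1.2). The inside probes are the dimmer probes of their genes, since the brightest stood for the gene. The rest of the 98 genes have no inside probe and were not tested. A fault near the edge at position 4 of each slide may account for these falls, and since position and group are one, why it arose was not tested.

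The glucocorticoid-response list in Scriptaid animals was set against time of day, surface trends and a general inhibitor response. A surface trend is argued against as the whole cause, since at least 98% of the median was kept when edge spots and trends were removed (adjusted p = 3.61e-11). A score of 6 late and 2 early clock genes differed by -0.29 in empty-vector legs (95% interval -0.75 to 0.20, exact permutation p = 0.23) and by -0.08 in dnHDAC4/5 legs (-0.45 to 0.23, p = 0.627), which leaves a shift in the time of collection open. The list of general inhibitor-response genes had an adjusted p of 0.203 in empty-vector legs and 0.0118 in dnHDAC4/5 legs, which decides nothing either way. Stress of the injected animals, or an action of Scriptaid on glucocorticoid signalling, could give the same list, and neither was tested.

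The genes changed by the vector in both sets of animals were set against chance, surface trends and the side of the body. Of 1024 swaps of legs within animals, a share of 0.0723 gave a correlation between the sets as high as the real 0.20 (highest other 0.32), so chance is not excluded for the agreement across all genes. The share was 0.0527 without edge spots (correlation 0.26) and 0.0469 with trends also removed (0.27), which lies on both sides of 5%. A smooth surface trend is argued against as the cause for the 34 genes called without edge spots. Of these, 100% kept at least 75% of their change when trends were removed and 70.6% were still called. The removed trends were small against most of these changes, and the test does not see local faults of the surface. The side of the body stays open, because 0 animals had the dnHDAC4/5 vectors in the left leg. So does the place on the slide, which was fixed for each group. An effect of the vectors on Chrna9, Igfn1 and the others is a hypothesis that may hold beside these.

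Other splits of the same arrays into groups of the same size, 100 drawn for each comparison, show how often other groupings gave as many genes. For the averaged vector effect, where legs were swapped within animals, 1 split, the real one, gave as many genes (172, highest other 165). Without edge spots 2 did (34, 42). These shares lie under 0.05. In both fits the highest other split swapped only the legs EV 5 and HV 5, and it gave nearly as many genes or more. Chance is therefore less likely for these counts but is not excluded. As many genes as the real split came from 1 split, the real one, for Scriptaid in dnHDAC4/5 legs (202, highest other 158) and the interaction (28, 1), and from 2 for both treatments against neither (376, 403; without edge spots 17, 194, also from 2). These shares count against chance only if arrays of one slide are exchangeable with others, since these splits ignore the slide. Splits within slides are too few for a share under 0.05. Because HS arrays share the edge fault, these counts measure that fault too. Without edge spots it was 11 for Scriptaid in dnHDAC4/5 legs (1, 47), and chance is not excluded. For the vector in vehicle animals and Scriptaid in empty-vector legs limma called 0 genes, with 729 and 603 at an unadjusted p under 0.05. All 100 splits gave as many (highest other 2 and 0). A real count of 0 makes that certain, so these splits decide nothing. The splits with 47 and 194 genes put HS 2 in the other group, in exchange for HV 4 and EV 3, and several times the real count points to a structure of the samples, HS 2 among them. For the vector in Scriptaid animals 1 split, the real one, gave as many genes with all spots (195, highest other 9) and without edge spots (3, highest other 2). Most of these splits break the pairs of legs, and the 12 drawn that part every pair, of which 1, the real one, gave as many, are too few for a share under 0.05.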

How the results depend on the processing

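The fits without edge spots, alone or with trends removed, a block or an array left out, were chosen only after the data were seen. The counts of 0 for the vector in vehicle animals held in every alternative except the fit without HV 5 (3 genes by limma), and for Scriptaid in empty-vector legs except without a filter on dim probes (1) and without EV 1 or EV 3 (1 each). The other counts moved by more than 1.5 times under some alternatives. Unless a cause is given below, the cause was not tested.

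For the vector in Scriptaid animals the count was 71 with series-matrix values, 322 without a filter on dim probes, 79 with a filter on all 20 arrays, 304 with every probe on its own, 359 with the slide as a block and 53 with only the groups compared. For Scriptaid in dnHDAC4/5 legs it was 89, 113, 316, 376 and 49 with series-matrix values, the filter on all arrays, every probe, the slide block and only the groups compared. For both treatments it was 1441 with normexp, 242 without a filter, 587 with every probe, 674 with the slide block and 63 with only the groups compared. For the averaged vector effect it was 72 without a filter, 287 with every probe, 267 with the replicate block, 405 with the slide block and 274 with array weights. For the interaction it was 83 with normexp, 3 with series-matrix values, 1 with the filter on all arrays, 49 with every probe and 46 with array weights. The balance of directions moved too. For the vector in Scriptaid animals it was 84 higher and 111 lower, but 13 and 218 with normexp, 58 and 21 with the filter on all arrays and 15 and 38 with only the groups compared. For Scriptaid in dnHDAC4/5 legs it was 100 and 102, but 9 and 200, 95 and 18, and 7 and 42 in the same fits. For both treatments it was 208 and 168, but 210 and 71 with series-matrix values, 198 and 65 with the filter on all arrays and 15 and 48 with only the groups compared. For the averaged vector effect it was 82 and 90, but 52 and 149 with normexp. Fewer arrays enter the fit of only the groups compared, and the series matrix and the filter on all arrays leave out dim probes, so fewer genes were tested.

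Without edge spots the counts for the vector in Scriptaid animals, Scriptaid in dnHDAC4/5 legs, both treatments, the averaged vector effect and the interaction were 3, 1, 17, 34 and 0. With trends also removed they were 2, 2, 17, 30 and 0, with the replicate block 1, 0, 10, 59 and 0, and with the slide block 2, 18, 195, 133 and 0. At an unadjusted p under 0.05 limma gave 316 genes for the interaction without edge spots. Leaving out each array, with or without edge spots, the counts ranged from 0 to 380, 0 to 476, 0 to 776, 11 to 330 and 0 to 57 in that order, the highest of all but the averaged effect being those without HS 2. For the averaged effect the highest was without HV 5 and the lowest without HV 1 or HV 2.

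The number of lists called, in the order vector in vehicle animals, vector in Scriptaid animals, Scriptaid in empty-vector legs, Scriptaid in dnHDAC4/5 legs, both treatments, averaged vector effect and interaction, was 6, 6, 10, 9, 6, 5 and 5. With an estimated correlation it was 0, 0, 1, 1, 1, 0 and 0, the 1 being the glucocorticoid list each time. With fry it was 0, 1, 2, 3, 7, 2 and 0. With quantile normalization red blood cell markers lost their call for the vector in vehicle animals, atrophy and autophagy genes and immediate early genes for Scriptaid in empty-vector legs, inhibitor-response genes for both treatments, and slow-fibre genes and Schwann-cell markers for the interaction. The interaction had 3 lists with quantile normalization and 2 with the replicate block (3 with edge spots also left out). Both treatments had 6 with quantile normalization and 10 with the replicate block (11 with edge spots also left out). Leaving out each array gave 5 to 10, 2 to 7, 5 to 11, 7 to 12, 7 to 11, 3 to 8 and 0 to 9. With the replicate block the fast-fibre list, which holds Casq1, was also called for the vector in Scriptaid animals (adjusted p = 0.0125), both treatments (0.000684) and the interaction (0.000797). The endothelial list, which holds Cdh5, was then called for Scriptaid in dnHDAC4/5 legs (0.004), both treatments (0.00903) and the averaged vector effect (0.00229). So were macrophage markers (0.0369) for the vector in vehicle animals, fatty acid genes (0.0446) and p53 targets (0.0497) for both treatments, and p53 targets (0.0496) for the averaged effect. Among named genes the block of animals ended the calls of Blnk (0.053), Ssbp4 (0.0513), Bhlhe40 (0.0606), Ggt6 (0.0631), Kcnc4 (0.0546), Chrnb1 (0.0859), Rttn (0.117), Far1 (0.0745) and Clta (0.286). Beside these and the values given with the comparisons it changed no other call with all spots. When edge spots were also left out, the block ended the call of Slc16a12 for Scriptaid in dnHDAC4/5 legs. It then also gave fewer genes for the vector in Scriptaid animals and for both treatments. With the slide block Ivd (0.00348) was called for Scriptaid in dnHDAC4/5 legs, Tomm34 (0.044) and Nr1i3 (0.0139) for the interaction, and Chrnb1 (0.0715) and Clta (0.0529) were lost. Of the lists, extracellular matrix genes and macrophage markers were then called for the vector in vehicle animals (0.0382 each) and for both treatments (0.0387 each), as were fatty acid genes for both treatments (0.0293). Without edge spots branched-chain amino acid genes (0.0273) and Schwann-cell markers (0.0189) were called for Scriptaid in dnHDAC4/5 legs, extracellular matrix genes and macrophage markers (0.0394 each) for both treatments, and cell cycle genes (0.00778) for the interaction. With an array left out, the similarity of the effects ranged from 0.37 to 0.55; it was 0.35 with the filter on all 20 arrays and -0.11 on average with the EV arrays split. With an array left out, the agreement between injections ranged from 0.14 to 0.26; it was 0.26 without edge spots, 0.27 with trends also removed and 0.33 with the filter on all 20 arrays.

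Of 275 results for named genes, normexp kept 213, weakened 46, strengthened 2 and reversed 14, and the median of all genes in the interaction was 0.12 with it, against 0.03. It was not run on lists. At an unadjusted p under 0.05 it gave 3547 genes for the vector in vehicle animals and 5770 for Scriptaid in empty-vector legs, against 729 and 603, with 0 called by limma in each. Of 322 results for named genes and lists, quantile normalization kept 311 and the replicate block 301, with 17 weaker, 3 stronger and 1 reversed. For named genes series-matrix values kept 193 of 228, the fit of only the groups compared 196 of 241 and the fit without edge spots 216 of 272. Over 3660 results for genes and lists with an array left out, 3332 were kept, 291 weaker, 19 stronger and 18 reversed.

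Reversals among values near 0 were those of Hdac4 and Hdac5. Hdac5 for the vector in vehicle animals was 0 with quantile normalization, 0.29 with normexp, 0.09 with series-matrix values, 0.01 with the slide block with or without edge spots and 0.17 with trends removed, and -0.18 to 0.06 with an array left out. In Scriptaid animals it was 0 with normexp, 0.05 with array weights and -0.12 to 0.08 with an array left out. Hdac4 for Scriptaid in empty-vector legs was 0.23 with normexp, 0.07 with series-matrix values and with trends removed, and -0.07 to 0.13 with an array left out. In dnHDAC4/5 legs it was -0.04 with quantile normalization, -0.06 with series-matrix values, -0.02 with the replicate block with or without edge spots, -0.1 with the slide block with or without edge spots, -0.03 with array weights, and -0.17 to 0.19 with an array left out.

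With normexp, Tlr5 (-0.22) and Chrng (-0.51) reversed for the vector in vehicle animals, Sik1 (-0.27) for Scriptaid in empty-vector legs, Harbi1 (-0.15), Tob1 (-0.14) and Actn3 (0.05) in dnHDAC4/5 legs, and Clta (-0.33), Tomm34 (-0.13), Slc16a12 (0.29), Cacnb2 (0.64) and Zfhx4 (0.37) for the interaction. With the mean of all probes of a gene Chrng was -0.5 and Eif4ebp1 -0.05 for the vector in vehicle animals, and Zmpste24 0.12 for the interaction.

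Other reversals were of edge probes, where the alternative took a probe inside the array or left the low spots out. For the vector in Scriptaid animals Mrpl1 was 0.03 with series-matrix values and 0.12 with the filter on all arrays and without edge spots (with either block too), Ccdc41 0.18 in the same fits without its series-matrix value and 0.13 with trends removed, Stx2 0.27 with series-matrix values, 0.16 without edge spots (with either block too) and 0.15 with trends removed, and Tek 0.29 with series-matrix values and 0.08 with the filter. For Scriptaid in dnHDAC4/5 legs Mrpl1 was 0.02 with series-matrix values and 0.07 with the filter and without edge spots (with either block too), Rpl21 0.25 with the filter and Ano6 0.03 with trends removed. For both treatments Med1 was -0.13 without edge spots (with either block too) and -0.15 with trends removed, Ccdc41 0.07 with the filter and without edge spots and 0.18 with trends removed, and Rpl21 0.45 with the filter. For the averaged vector effect Chd1 was 0 with the filter and without edge spots and 0.08 with trends removed, and Ccdc41 0.03 with trends removed. For the interaction Ccdc41 was 0.38 with the filter and without edge spots and 0.19 with trends removed, Rttn -0.16 with trends removed, Rpl21 0.39 with the filter, and Zmpste24 0.56 with series-matrix values, 0.72 with the filter and without edge spots, 0.58 with trends removed and -0.91 to 0.63 with an array left out (0.63 without HS 5).

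Signal over background limits Chrna9, Fam150b and Rgs11, whose lower group was under background, so that their changes are bounds. Between 51.7% and 61.3% of spots were well above background on an array.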

Other observations

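Chrna9, Pla2g5 and Igfn1, a receptor subunit, a secreted phospholipase and a protein of the Z-disc, rose with the vectors in 10 of 10 animals. Chrna9 was not well above background on any of the 10 empty-vector arrays, nor on every HV array. The lists of atrophy and autophagy genes and of heat shock proteins had medians of 0.25 and 0.38 over both injections, but neither passed with an estimated correlation (adjusted p = 0.328 and 0.172). Whether the vectors, the side of the body or the place on the slide brought this about cannot be told apart. The reason is that 0 animals had the dnHDAC4/5 vectors in the left leg, and each group kept its place on every slide.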
